A study of Escherichia coli K-12 and Salmonella enterica with 12 samples.

How the data were processed

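PT-nick-seq measured breaks in genomic DNA of E. coli BW25113 and JW3350 and of S. enterica YF11 in 12 libraries. Per the labels' protocols, DNA was cut with 3 mixes of restriction enzymes, existing breaks were blocked with dideoxynucleotides, iodine was applied to the treated sample, and libraries were made with a SMART kit and 12 cycles of PCR. Each sample was size selected together with its own control. The submitters' processing notes name Trim Galore, Bowtie2 and bedtools; versions, settings and the order of steps are not given in the sources used here.

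Values in CPM are counts of 5' ends scaled to the same total in every library. For every library the authors deposited, per strand and per base of the chromosome, whole-number counts of read 5' ends and a coverage signal. The counts were not normalized, per the values themselves, whose totals differ between libraries from 338851 to 6996545 5' ends. The deposited coverage held 119 to 125 bases per 5' end, while the labels give paired reads of 75 bases; what length each 5' end covers is not given in the sources used here. The coordinates are those of the deposited files. They name the chromosome sequences only by accession, and no genome sequence or annotation of that build was used here. The planned results that needed a sequence or gene positions were therefore not run. These were the shares of 5' ends and called positions at GAAC/GTTC, the test of GATC sites, the Fisher tests between plasmids, the gene lists and the genes holding named positions. Position-based measures took their place and were chosen after the data had been examined, as were the definition of a site, the classes of gained, lost and shared sites, the scan for the deleted interval and the regions of raised depth.

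By a rule written before the data were examined, a strand position was called where the iodine count was at least 10, at least 2 times the higher adjacent position on that strand, and at least 2 times the control after division by the total 5' ends of each library, with no pseudocount. A local peak met the first 2 conditions. A site was a called reverse position with a called forward position 3 bases higher; this distance was read from the data. Shares carry exact Clopper-Pearson intervals at 95%, and the limit for a count of 0 is 3 counts of the total. Iodine and control were compared over the 6 pairs with an exact two-sided sign-flip permutation test. A gained site was a site in JW3350 pJTU1238 with at least 4-fold higher CPM, after adding 0.5 to the counts, than in each BW25113 iodine library. A lost site was a site in both BW25113 pairs with at least 4-fold more in each than in JW3350 pJTU1238. A narrower definition had been tried first, sites with neither strand called in BW25113, and gave 2226 gained sites. The deleted interval was sought in windows of 500 bases moved by 50 bases, with mean depth under 0.25 times the chromosome median in all JW3350 libraries and above 1 times in both BW25113 iodine libraries. The planned search for runs of at least 500 bases with zero depth found the interval in both JW3350 controls, but not in the iodine libraries, where the longest runs there were 455 and 271 bases. It also found many other runs in the JW3350 pJTU1238 control and in the JW3350 pJTU1980 iodine library. Only in the JW3350 pJTU1980 control did it single out the interval.

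S. enterica positions with a total of at least 20 counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, limma 3.58.1, R 4.3.3), with total 5' ends as library size and no further factor or block; a second fit took the replicate as a block, as each sample shared size selection with its own control. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F value. DESeq2 1.42.0 was the alternative. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The named positions followed a rule fixed before the data were examined. It took the 10 positions with the highest lower value of the 2 plasmids among those called in both pairs of a strain, the 10 highest called in JW3350 and in neither BW25113 pair, and in S. enterica the 10 highest by mean that passed edgeR and were called in both pairs. The condition of lying at GATC could not be applied. Example sites of the gained and lost classes were taken from the 10 strongest of each class after the values were seen.

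The calling rule was tested on simulated libraries of 800000 strand positions with planted sites. It recovered 0%, 37.5% and 100% of sites with a mean of 5, 10 and 20 5' ends per strand, and with independent background in iodine and control it also called 1761 single positions and 3 sites that had not been planted. Of 100 simulated gained sites 97 were found, and 0 of 100 unchanged sites was called gained. These sites were strong, the gained ones were raised 8-fold, and the simulated libraries had equal depth and counting error only. The result thus gives no rate of false gained sites in the data. There the same rule gave 751 and 749 sites higher in a BW25113 library than in the other libraries. For the S. enterica comparison, counts simulated for the 44359 positions at a dispersion of 0.138 gave 0%, 22%, 74% and 100% recovery of positions raised 2, 4, 8 and 16-fold, with 4 calls among 44159 unchanged positions. Chi-square over degrees of freedom between replicates was 6.51 for iodine and 15.6 for control, so that the replicates differed by more than counting error.

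Alternatives planned before the data were examined were a count minimum of 5 or 20, 5 times the adjacent positions, 5 times the control, a control count plus 1, libraries thinned to 2111600 (iodine) and 338851 (control) 5' ends, a limit of 50 per position, leaving out the JW3350 pJTU1980 pair or exchanging its labels, and in S. enterica TMM factors, DESeq2, other count filters, the replicate as a block, leaving out each library and matching within 1 base. Added after seeing the data were folds of 2 and 8, the narrower definition of gained sites, centring on sites shared by the BW25113 plasmids, totals without the 100 highest positions of any library, and the highest of 25 distances within each permutation.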

Results

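Phosphorothioate (PT) modification replaces a non-bridging oxygen of the DNA backbone with sulfur and is carried out by the Dnd proteins. Sites were mapped by PT-nick-seq, in which iodine breaks the backbone at PT links and the read 5' end marks the break. The 12 libraries formed 6 pairs of an iodine-treated sample and an untreated control. In Escherichia coli, which received the Salmonella DndBCDE proteins, 4 pairs covered the wild type BW25113 and the dam deletion mutant JW3350, each with plasmid pJTU1238 or pJTU1980. Each of these groups held 1 library, so no difference between E. coli groups has a replicate check. In Salmonella enterica serovar Cerro 87, 2 replicate pairs came from YF11, a dndC deletion strain carrying Flag-tagged DndC.

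The iodine libraries held 3421934 5' ends for BW25113 pJTU1238, 5000568 for BW25113 pJTU1980, 2111600 for JW3350 pJTU1238 and 6125871 for JW3350 pJTU1980. Their controls held 398933, 942787, 338851 and 4726829 in the same order. The S. enterica iodine libraries held 3719170 and 6996545 5' ends and their controls 3213636 and 2060505. A few strand positions took a large part of every library. Of the 10 highest positions of each E. coli library, 8 were common to all 8 libraries, controls included, and in S. enterica 9 were common to all 4 libraries. These 10 positions held 11.3% to 13.1% of the 5' ends in 3 of the E. coli iodine libraries, 65.5% in the JW3350 pJTU1980 iodine library and 37.7% to 50% in the E. coli controls. The JW3350 pJTU1980 iodine library had 5' ends at 89246 strand positions, against 418999 in its control.

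The deletion carried by JW3350 was looked for first, as a check of the labels. Of 92620 overlapping windows of 500 bases on the E. coli chromosome, those that were depleted in all 4 JW3350 libraries and covered in both BW25113 iodine libraries formed 1 interval, from 3508601 to 3509250. Mean depth in this interval of 650 bases was 113 and 213 in the BW25113 iodine libraries with pJTU1238 and pJTU1980. It was 0.208 in the JW3350 pJTU1238 iodine library, from 1 5' end against 2664 in the 5 kb on either side. In the JW3350 pJTU1980 iodine library it was 0.502, or 8.28% of the flanking depth of 6.06, from 3 5' ends against 482. The JW3350 controls had a mean depth of 0 with pJTU1238 and 0.0292 with pJTU1980, where the flanks had 4.29 and 45.9. Gene positions of this build were not used here, so the interval was not matched to dam by annotation.

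PT links on both strands of one short sequence place a break on each strand at a fixed distance. Local peaks of 5' ends in the iodine libraries lay on both strands at 1 distance, with the forward position 3 bases above the reverse position. Of the forward peaks, 55.3% (95% exact binomial interval 54.6% to 56.0%) had such a partner in BW25113 pJTU1238 and 58.7% (58.1% to 59.4%) in BW25113 pJTU1980. The share was 47.5% (46.7% to 48.3%) in JW3350 pJTU1238 and 6.21% (5.47% to 7.01%) in JW3350 pJTU1980. In the S. enterica replicates it was 40.4% (39.6% to 41.2%) and 45.1% (44.5% to 45.8%). In both BW25113 controls no forward peak had a partner at this distance, 0 of 875 and 0 of 1045, which allows shares of up to 0.343% and 0.287%. The other controls had shares of 0.0349% to 0.195%, including 0.145% of the 17210 forward peaks of the JW3350 pJTU1980 control. The share was higher with iodine in 6 of 6 pairs, by a mean of 42.1 percentage points (SD 18.9, n = 6; exact two-sided sign-flip permutation test, p = 0.03125, the smallest that 6 pairs can give). The distance was read from these same libraries; with the highest of 25 distances taken within each permutation the exact p was also 0.03125, and the other 5 pairs picked 3 bases for each pair. Intervals and limits of this kind cover counting error only, because PCR copies were not told apart.

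**Figure D1:**
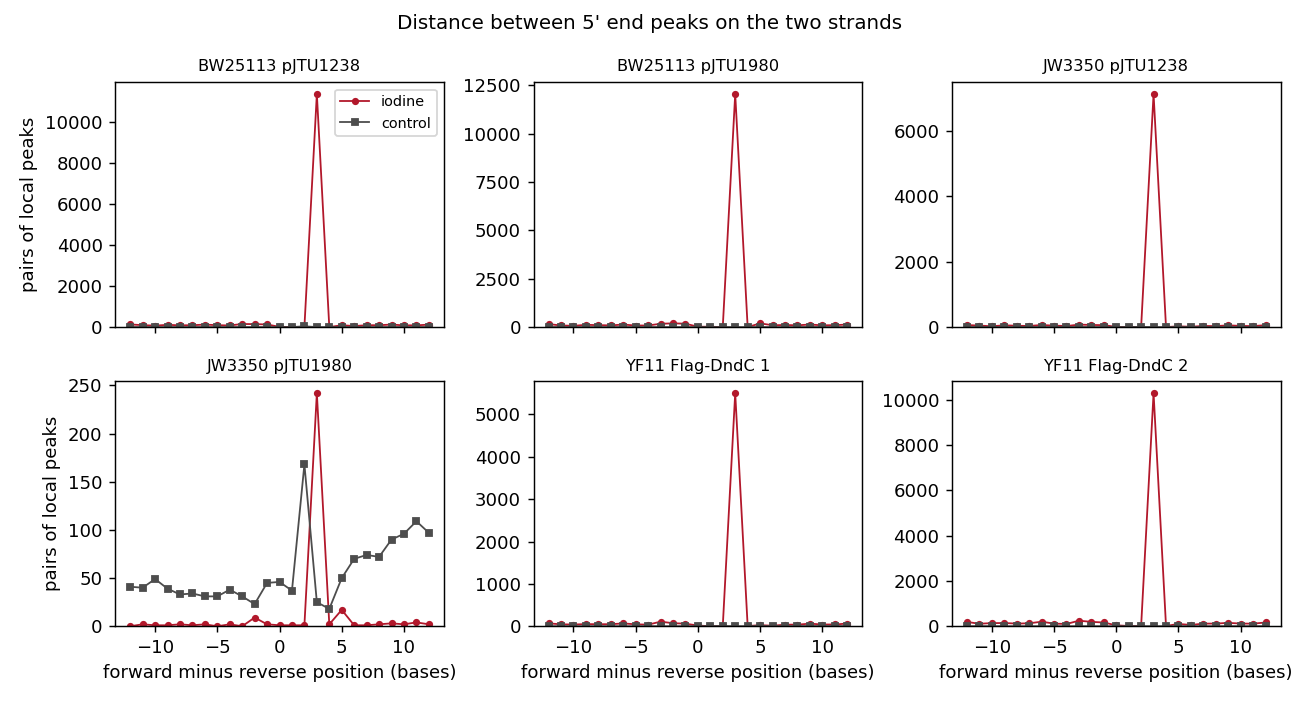
Number of pairs of local 5' end peaks (vertical axis) against the forward position minus the reverse position in bases (horizontal axis), for iodine (red circles) and control (grey squares) libraries of the 6 pairs; vertical scales differ between panels. A single maximum lies at 3 bases in every iodine library, with 11386, 12044, 7133, 242, 5502 and 10296 pairs in panel order.

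The iodine libraries were then compared with their own controls to find modified positions. The number of called strand positions was 39314 in BW25113 pJTU1238, 38553 in BW25113 pJTU1980, 28724 in JW3350 pJTU1238 and 5847 in JW3350 pJTU1980. The S. enterica replicates gave 25320 and 41837. In the libraries thinned to equal depth, BW25113 pJTU1238 gave 29895, BW25113 pJTU1980 24948 and JW3350 pJTU1238 28724. The ranking of BW25113 pJTU1980 and JW3350 pJTU1238 thus turned with depth. With the roles of iodine and control exchanged in the full libraries, the same rule gave 1676, 1867, 919, 33013, 4626 and 2852 positions in the same order of pairs. Strand positions with at least 10 5' ends in the controls numbered 2068, 2727, 1254, 40090, 7666 and 4605. The exchanged counts thus depend on control depth and give no rate of false calls. Called positions that lay on both strands 3 bases apart are counted below as sites. BW25113 had 11172 sites with pJTU1238 and 11957 with pJTU1980, JW3350 had 7068 with pJTU1238 and 232 with pJTU1980, and the S. enterica replicates had 5498 and 10237. With the roles exchanged there were at most 24 such sites, in the JW3350 pJTU1980 pair. The median spacing of neighbouring sites was 292 bases in BW25113 pJTU1238, 287 bases in BW25113 pJTU1980 and 474 bases in JW3350 pJTU1238. Spacing and number of sites depend on depth, which was lowest in JW3350 pJTU1238 by total iodine 5' ends. In the thinned libraries 50.1%, 55.3% and 49.2% of called positions lay in sites, in the order of these pairs. A lower number of sites in JW3350 pJTU1238 thus cannot be told from its lower depth. Among forward positions called without their partner, 53.2% to 72.5% still had at least 1 reverse 5' end at the partner position in the pairs other than JW3350 pJTU1980, where the share was 23.8%.

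Of all 5' ends, 43.9% in the BW25113 pJTU1238 iodine library fell on sites called in the other E. coli pairs, against 0.776% in its control. The shares were 41.6% against 0.543% in BW25113 pJTU1980, 28.6% against 0.511% in JW3350 pJTU1238 and 1.44% against 0.274% in JW3350 pJTU1980. The S. enterica libraries, each measured on sites of the other replicate, had 26.5% and 23.8% with iodine and 0.208% and 0.199% without. The mean difference over the 6 pairs was 27.2 percentage points (higher with iodine in 6 of 6; exact two-sided sign-flip permutation test, p = 0.03125).

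The plasmid comparison asked how far pJTU1238 and pJTU1980 gave the same map; the labels do not say how they differ. In BW25113, 29045 positions were called with both, 73.9% of those called with pJTU1238 and 75.3% of those called with pJTU1980. Independent lists among the 56217 positions with at least 10 5' ends in either library would share 26961, and lists drawn from all strand positions 164. The 56217 include positions that reached 10 in 1 library only and so could not be called in the other. The value of 26961 is therefore too high to serve as a chance level. The value of 164 in turn counts every strand position, covered or not. Of 15138 sites called with either plasmid, 1845 were at least 4-fold higher with pJTU1238 and 910 at least 4-fold higher with pJTU1980 in a binomial test that compares these 2 libraries. Across sites, which are not independent replicates, the Spearman correlation between the plasmids was 0.574. The reverse position 341102 had 2231 and 2553 CPM (counts of 5' ends scaled to a common library total) with pJTU1238 and pJTU1980, against 25.1 and 19.1 in the controls. The forward position 2839563 had 1447 and 3385 CPM, and the reverse position 1709006 had 4882 and 1170 CPM. In all, the 10 strongest shared positions had 608 to 4882 CPM with pJTU1238 and at most 60.2 CPM in its control. In JW3350 the plasmids shared 3269 called positions, 55.9% of those called with pJTU1980. Independent lists would share 4610 among positions with at least 10 5' ends in either library, and 18.1 among all strand positions. The same limits hold for these values, so 3269 against 4610 does not show an overlap below chance. The overlap of 3269 is limited by the JW3350 pJTU1980 library, in which 2160 of the called positions were called in no other E. coli pair.

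The question of the dam comparison was where modification appears when Dam, the adenine methyltransferase acting at GATC, is absent. JW3350 pJTU1238 and BW25113 shared many sites, but a separate class of sites carried far more iodine 5' ends in the mutant. Of the 7068 sites in JW3350 pJTU1238, 2946 (41.7%) were at least 4-fold higher in CPM than in both BW25113 iodine libraries and are called gained here. In 2203 of these neither strand was called in either BW25113 pair. With a count minimum of 5 or 20 in place of 10, gained sites numbered 4976 and 1355. Gained sites had a mean of 45.7 CPM in JW3350 pJTU1238, against 3.08 in BW25113 pJTU1238 and 1.08 in BW25113 pJTU1980, and 0.502 in the JW3350 pJTU1238 control. Another 3168 sites were called in JW3350 pJTU1238 and in both BW25113 pairs, with means of 46.6, 61.4 and 62.0 CPM. All 2946 gained sites passed a binomial test against each BW25113 library (Benjamini-Hochberg threshold of 0.05), which compares libraries and not strains. The sites were selected for a 4-fold difference in these same counts, so passing this test adds no support. The same rule applied to the BW25113 libraries, as a measure of the spread between libraries, gave 751 sites higher in BW25113 pJTU1238 than in the other libraries and 749 higher in BW25113 pJTU1980.

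The strongest gained site, at reverse position 4130683 and forward position 4130686, had 788 CPM in JW3350 pJTU1238, 52.9 in BW25113 pJTU1238 and 9.20 in BW25113 pJTU1980. The site at 2701699 and 2701702 had 679, 11.7 and 2.00 CPM, and the site at 1174337 and 1174340 had 528, 13.7 and 1.20. Among the 10 strongest gained sites, the JW3350 pJTU1238 value was 4.07 to 80.1 times that of BW25113 pJTU1238 and 15.8 to 406 times that of BW25113 pJTU1980. The more frequent strand held 89.9% to 99.3% of the 5' ends at these 10 sites. The sites were spread over the chromosome, with a mean of 63.7 gained sites per 100 kb (SD 9.50 over 46 windows, range 46 to 84).

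Sites called in both BW25113 pairs were lower in JW3350 pJTU1238 as a whole, with a median log2 ratio of -1.14 (SD 1.32 over 7991 sites). Relative to library totals, 1381 of them were at least 4-fold lower in the mutant than in both BW25113 libraries. Centred on that median, 349 were at least 4-fold lower and 3553 sites were at least 4-fold higher, so the number of lost sites depended on the scaling. The sites behind this median were chosen by their BW25113 calls alone, which favours lower values in JW3350. At the 3168 shared sites, which were called in JW3350 pJTU1238 as well, the median log2 ratio was -0.304. A lost site at reverse position 2965492 and forward position 2965495 had 604 and 607 CPM in BW25113 with pJTU1238 and pJTU1980 and 59.2 in JW3350 pJTU1238.

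**Figure D2:**
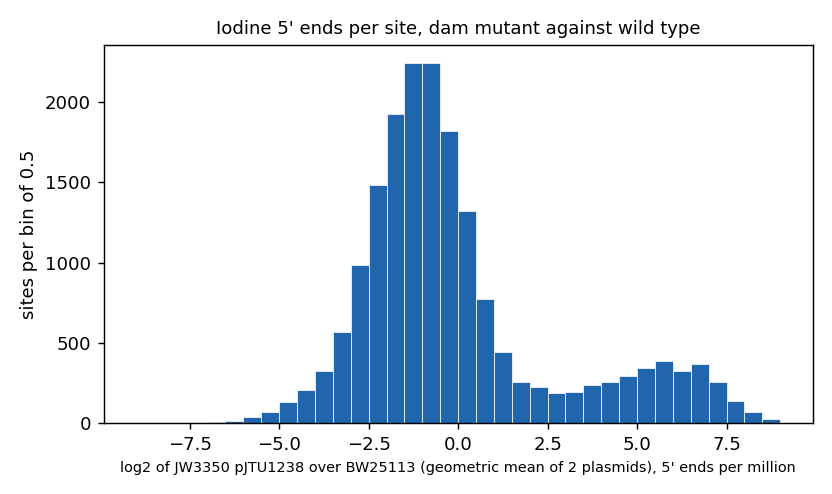
Histogram of 18198 sites called in BW25113 pJTU1238, BW25113 pJTU1980 or JW3350 pJTU1238, by the log2 ratio of JW3350 pJTU1238 to the geometric mean of the BW25113 iodine libraries (horizontal axis, from CPM); the vertical axis gives sites per bin. Most sites form a peak near the median of -1.14 of the BW25113 sites, and 3107 sites lie above 2.5.

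The JW3350 pJTU1980 iodine library, which was not used to define these classes, had a mean of 7.66 5' ends at gained sites, 10.1 at shared sites and 3.50 at lost sites. At the gained positions moved by 50 bases it had 0.0567. On the scaling that defines gained sites there was no 4-fold rise in this library: gained sites had a mean of 1.25 CPM, against 1.08 CPM in BW25113 pJTU1980 and 3.08 CPM in BW25113 pJTU1238. Gained sites were chosen to be low in both BW25113 libraries, which lowers the BW25113 values in this comparison. Of the 10 strongest gained sites, 7 were higher in CPM than in BW25113 pJTU1980 and 3 higher than in BW25113 pJTU1238. Of the positions called in JW3350 pJTU1238 and not in BW25113, 7.74% (816 of 10537) were also called in JW3350 pJTU1980. Of those called in BW25113 and not in JW3350 pJTU1238, 1.36% (418 of 30635) were, and of those called in both strains 13.5% (2453 of 18187). By the selection fixed before the data were examined, the 10 strongest positions called in JW3350 and in neither BW25113 pair were all called in the pJTU1980 pair. None had a called partner, and all were also high in that pair's control, at 1176 to 31614 CPM against 4173 to 96798 with iodine.

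In S. enterica, the question was which positions rose with iodine over both replicates. Of 44359 strand positions tested with edgeR's quasi-likelihood test, 33980 were higher with iodine and 4411 lower at a Benjamini-Hochberg adjusted p below 0.05 (n = 2 libraries per group). Of the lower positions, 4406 were called in no pair, which follows largely from the rule, since a call requires an excess over the control. With the replicate as a block 25812 were higher and 2723 lower, and DESeq2 gave 1895 lower. Leaving out the second iodine replicate reduced these counts to 16940 and 1400, and leaving out the first to 20337 and 1653. The 23561 positions called in both pairs, which the rule already requires to exceed the control, had a median log2 fold change of 7.14. The reverse position 139820 was the strongest, at 12673 ± 2298 CPM with iodine (SD, n = 2) against 37.0 and 67.9 in the controls (log2 fold change 7.92, SE 0.43, edgeR adjusted p = 3.12e-71). The forward position 173953 followed with 2006 ± 486 CPM (log2 fold change 7.33, SE 0.51, edgeR adjusted p = 3.96e-42). Of the 10 strongest positions, 9 lay between 131496 and 173953, and the other was the reverse position 3904569 with 1163 ± 88.5 CPM. This ranking was not corrected for read depth, which was raised from 130001 to 180000 in the controls as well. The labels do not say whether the replicates were separate cultures, so these p-values measure the spread between these libraries, which may be technical.

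The replicates shared 23561 called positions, 93.1% of the first list and 56.3% of the longer second list. Independent lists among the 51637 positions with at least 10 5' ends in either replicate would share 20515. The 51637 include positions that reached 10 in 1 replicate only and so could not be called in the other. The value of 20515 is therefore too high to serve as a chance level. Lists drawn from all strand positions, covered or not, would share far fewer. Of the 5498 sites in replicate 1, 5144 were also sites in replicate 2. Across the 10591 sites of either replicate the Spearman correlation of 5' ends was 0.900, across sites that are not independent replicates.

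Sites were unevenly spread on the S. enterica chromosome. Windows of 100 kb held a mean of 120 sites (SD 45.2) in replicate 1 and 223 (SD 47.7) in replicate 2. The window from 100001 to 200000 was the highest in both, with 333 and 419 sites, and its median iodine depth was 4.8 and 3.59 times the chromosome median. Site counts were not corrected for depth, although a fixed count minimum is met more easily where depth is high. Read depth was raised over 50 kb from 130001 to 180000, to 9.85 and 11.7 times the chromosome median in the iodine libraries and to 6.33 and 8 times in the controls. A second interval from 235001 to 285000 had 2.50 and 2.22 times the median depth with iodine and 3.22 and 2.60 times without. In E. coli the highest window of 100 kb had 336 sites in BW25113 pJTU1238 and 361 in BW25113 pJTU1980, and lay from 3400001 to 3500000 in both. Its median iodine depth was 1.37 and 1.34 times the chromosome median.

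**Figure D3:**
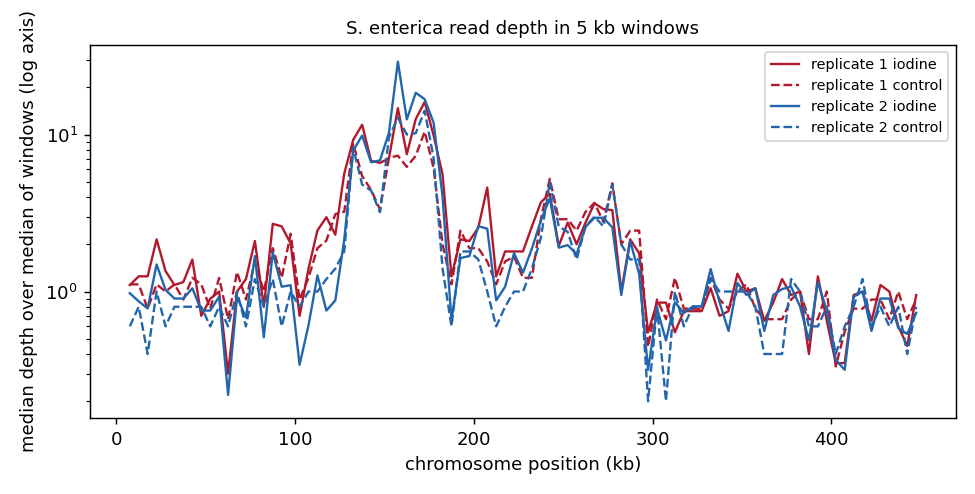
Median read depth of S. enterica libraries in 5 kb windows divided by the median of all windows (vertical log axis) along the first part of the chromosome in kb (horizontal axis), for replicate 1 (red) and replicate 2 (blue), iodine (solid) and control (dashed). All 4 lines rise together from 130 to 180 kb and, by less, in a second stretch that starts at 235 kb.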

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

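All tests of explanations in this part were chosen after the results were seen.

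Some low signal lay outside the main measurement. In the interval missing from JW3350, the pJTU1238 iodine library had a mean depth of 0.2077 against 0 in its control, and the pJTU1980 iodine library 0.5015 against 0.0292; these depths are not scaled and rest on 1 and 3 5' ends, so foreign DNA was neither shown nor excluded. Local peaks 5 bases apart on the strands numbered 192 in the BW25113 pJTU1980 iodine library and 0 in its control, which had 1045 forward peaks against 20502; another distance in the same iodine library had 194 pairs, so 5 bases did not stand apart there. In the JW3350 pJTU1980 iodine library 17 pairs lay 5 bases apart, against at most 9 at any other distance but 3, and its control had 50.

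A class of sites was at least 4-fold higher in the JW3350 pJTU1238 iodine library than in both BW25113 libraries. Spread between single libraries would give BW25113 a like number, but the highest count in a BW25113 library by the same rule was 751, against 2946. Too few 5' ends in BW25113 would leave fewer per shared site than in JW3350 pJTU1238, but the lowest mean in a BW25113 iodine library was 210, against 98.4. Shared sites were by definition called in both BW25113 pairs, so this mean cannot speak for gained sites. By library totals, the BW25113 iodine libraries held 3421934 and 5000568 5' ends, against 2111600 in JW3350 pJTU1238. Against a property of that single library, classes were taken from the pJTU1238 pairs alone. The ratio of JW3350 to BW25113 in the pJTU1980 libraries was then compared between classes. At sites higher in JW3350 it was 30.0 times that at sites within 4-fold (bootstrap interval over sites 26.7 to 33.6). This was a relative difference only. At these 3015 sites the mean was 7.65 5' ends in JW3350 pJTU1980 and 7.32 in BW25113 pJTU1980. These libraries held 6125871 and 5000568 5' ends in all, so on library totals JW3350 pJTU1980 was not higher there. Reads of the first JW3350 library assigned to the second, as the only source there, would follow the counts of the first. Chi-square over degrees of freedom was instead 10.7 at gained sites. A partial share of such reads stays open, since a mixture with the second library's own signal would also raise this value. A candidate explanation is that loss of dam opens a set of sites to PT modification; with 1 library per group, any other difference between the strains stays open, as does DNA of the first JW3350 library mixed into the second before amplification; neither was tested, nor was the sequence at these sites.

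Read depth on the S. enterica chromosome was raised between 130 and 180 kb. Iodine cutting would leave the controls flat, but the lower of the control ratios was 6.33. A few positions taking most of the reads would not raise the number of distinct 5' end positions per base, which was at least 3.84 times that of the rest in all 4 libraries. The values are consistent with a higher copy number of this stretch, for example a replicating mobile element, or with reads of another molecule that map there; neither was tested. The design gives no group without the raised depth, so no biological explanation was tested.

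The JW3350 pJTU1980 pair had a weak iodine signal and a control with many 5' ends. If the labels had been exchanged, the library labelled control would hold the peaks 3 bases apart; instead they made up 6.21% of forward peaks in the library labelled iodine and 0.145% in the one labelled control. The 10 highest positions took 65.5% of the 5' ends of the iodine library, but JW3350 pJTU1238 thinned to as many 5' ends as this library had outside its 100 highest positions still gave 3360 sites, against 232. The cause of the low yield stays open.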

How the results depend on the processing

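The folds, the narrower definition of gained sites, centring, totals without the highest positions and the highest distance within each permutation were chosen after seeing the data; the other alternatives were planned. The higher paired share and the higher share of 5' ends on sites with iodine kept their direction throughout. Without the JW3350 pJTU1980 pair the mean differences were 49.3 and 32.3 percentage points, with p = 0.0625 by the exact permutation test, the smallest that 5 pairs can give. With its labels exchanged they were 40.1 and 26.8 over 6 pairs (exact permutation test, p = 0.0625), as that pair then went the other way. With a minimum of 5, called positions numbered 60315, 60022, 48719, 14243, 43832 and 69976 in the order of pairs above, with 4976 gained, 2089 lost and 6162 shared sites, and 7113 positions shared in JW3350 and 35470 in S. enterica. With a minimum of 20 there were 25523 in BW25113 pJTU1238, 15954 and 1653 in JW3350, and 14623 and 26210 in S. enterica, with 1355 gained, 783 lost and 1316 shared sites, and 18990, 970 and 14141 positions shared in BW25113, JW3350 and S. enterica. Thinned, BW25113 pJTU1980 had 24948, JW3350 pJTU1980 1079 and S. enterica 16696 and 18734 called positions, with 864 lost sites and 607 and 13782 shared positions in JW3350 and S. enterica. A control count plus 1 left 882 lost, 2250 gained and 2113 shared sites. It left 26984 called positions in BW25113 pJTU1238 and 22909 in JW3350 pJTU1238, with 22385 positions shared in BW25113. Folds of 2 and 8 gave 3431 and 404 lost sites, and centring gave 349. With the JW3350 pJTU1980 labels exchanged, 33013 positions were called, of which 364 were shared with pJTU1238. These counts follow the minimum, depth or fold by construction; the cause of the other changes was not tested.

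In S. enterica a total of at least 50 counts, which tests fewer positions, gave 17788 higher and 1660 lower, and DESeq2 gave 1895 lower. With the replicate as a block, that is with paired libraries, 25812 were higher and 2723 lower; each sample was size selected with its own control, so the pairing is real for that step, while with 2 pairs the differences between replicates in iodine and control correlated at 0.0899 over positions. Leaving out 1 library in turn, with the lone library assumed to vary like the other group, gave 16940 to 33219 higher and 1400 to 3764 lower. With 5 times the adjacent positions, or totals without the highest positions, the counts of called, gained, lost and shared positions and sites stayed within the range given above. Of the 30 named E. coli positions 19 met their rule at 5 times the control. Simulated sites with a mean of 5 5' ends per strand were not recovered.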

Other observations

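The test of the 3-base spacing below was chosen after the pattern had been seen.

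Gained sites were not free of signal in the wild type, and the plasmids differed there. In BW25113 pJTU1238, 83.1% of gained sites had at least 1 iodine 5' end, with a mean of 3.08 CPM, and in BW25113 pJTU1980 57.8% had one, with a mean of 1.08 CPM. At the same sites moved by 50 bases the means were 0.0984 and 0.0794 CPM. The deeper library, pJTU1980, thus had the lower signal. The BW25113 pJTU1238 control had 0.106 CPM at gained sites.

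The balance between strands recurred between libraries, less so with JW3350 pJTU1980. Over sites called in both, the log2 ratio of forward to reverse 5' ends correlated at 0.899 between the BW25113 plasmids, at 0.848 between BW25113 pJTU1238 and JW3350 pJTU1238, and at 0.903 between the S. enterica replicates, but at 0.345 to 0.420 between JW3350 pJTU1980 and the other E. coli libraries, across sites that are not independent replicates. Its SD was 1.41 at shared sites and 1.52 at gained sites in JW3350 pJTU1238, where 14.8% and 17.3% of sites differed at least 4-fold between strands.

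Distances between sites favoured multiples of 3. Among 549 short distances, of at least 5 bases, between gained sites, 50.5% were divisible by 3 (permutation test in which each position was moved at random by up to 1 base, one-sided p = 1e-05, the smallest that 100000 resamples can give). By the same permutation test the share was 39.9% of 621 distances for shared sites (p = 0.00039) and 39.2% of 181 for lost sites (p = 0.0533). For BW25113 sites, the largest set, it was 40.4% of 14787 distances (same permutation test, p = 1e-05). The preference was thus not limited to gained sites. The difference between classes was not tested. A 3-base frame such as that of coding sequence may underlie the spacing, which gene positions of this build, not used here, would settle.

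In the JW3350 pJTU1980 control, 168 pairs of local peaks lay 2 bases apart, against 59.5 as the median at distances of 6 to 12 bases either way, and 39 pairs lay 2 bases apart in the BW25113 pJTU1238 control.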
